A study of Danio rerio with 9 samples.

How the data were processed

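Total RNA from whole wild-type zebrafish embryos of the Tuebingen strain was hybridised to Affymetrix arrays, 1 biotin-labelled sample per array. The labels place the embryos at the gastrula stage, about 8 h after fertilisation, and give 3 groups: exposure to 20 µg/L pentachlorophenol, exposure to 50 µg/L pentachlorophenol, and deionized water as the control. Each group held 3 arrays that the labels number 1 to 3 and call biological replicates, 9 arrays in all. The labels do not say how many embryos made a sample or whether the samples came from separate clutches, so the p-values measure only the spread between these samples.

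The deposited values are intensity values, 1 per probe set and array on a linear scale, for 15617 probe sets. Per the submitters' processing notes the authors used GCOS and MAS5, with versions not given in the sources used here. In the deposited table the mean of every array after trimming 2% at each end was 500.1 or 500.2, so each array had been scaled by the authors to the same trimmed mean. No further normalization between arrays was visible. The values of the arrays with number 3 carried more decimals than those of the other 6 arrays, and this difference in export was treated as a possible batch. Each batch held all 3 groups, but the batch of arrays with number 3 held only 1 array per group and so gave no test of its own. With this batch as a block the fold changes were the same by construction, since every batch held each group equally, and only their tests differed. No column of any other sample was in the table (0 such columns).

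Values were taken as log2(value + 1), and a fold change is on that scale. For dim probe sets such a change is not a lower bound, since several became smaller with dim values raised to a background level. The 115 control probe sets of the manufacturer and the 40% of the other probe sets with the lowest mean over all arrays were left out, which kept 9301 probe sets. The model was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts of the group means, eBayes with an intensity trend). Comparisons were 20 µg/L against control, 50 µg/L against control and 50 against 20 µg/L, each two-sided, with Benjamini-Hochberg adjustment over the probe sets kept and a threshold of 0.05. A moderated F test over both doses against control was adjusted the same way. Replicate numbers were not used as a block. The number of arrays limits the precision of every value.

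A dim probe set has no measured level. As a bound on background, the 95th percentile of the manufacturer's tag control probe sets was taken on each array. Where every array of the lower group was under this level, values below it were raised to it and the change is given as at least N-fold. Detection calls were not used here.

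Gene symbols came from the platform annotation and were updated through gene identifiers to the reference tables. Of the probe sets, 10802 matched 1 gene, 135 matched several and 4680 matched none, and the matched ones held 8781 genes. No gene was named from a probe set with several genes. For gene lists, the probe set with the highest mean over all arrays stood for its gene, which left 6112 genes tested. Other probe sets of a named gene are given where their calls differ from it. No genome coordinates were used.

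In all, 27 gene lists were fixed before the data were examined. They covered glycolysis and glucose uptake, pyruvate dehydrogenase and the TCA cycle, oxidative phosphorylation, mitochondrial uncoupling and biogenesis, the pentose phosphate pathway, the hypoxia response, oxidative stress and glutathione, and aryl hydrocarbon receptor and xenobiotic metabolism. Further lists were thyroid and steroid hormone signalling, heat shock and cytosolic chaperones, endoplasmic reticulum stress and amino acid response, growth arrest and apoptosis, cell cycle and DNA replication, cytosolic ribosomal proteins, ribosome biogenesis and nucleolus, and proteasome and ubiquitin. Embryonic lists were dorsal organizer and axial mesoderm, BMP pathway and ventral fate, ventrolateral and paraxial mesoderm, endoderm and Nodal pathway, neuroectoderm, segmentation-stage genes, enveloping layer and epidermal keratins, yolk syncytial layer and yolk transport, germ cells and maternal oocyte transcripts, convergent extension and epiboly, and lipid and cholesterol metabolism. Lists with at least 5 measured genes were tested with camera (limma) at a preset correlation between genes of 0.01, with adjustment over the 27 lists of a comparison. Camera asks whether a list moved relative to the other genes. Camera with an estimated correlation and the rotation test fry, which asks whether the genes of a list move one way on balance without reference to other genes, were run beside it.

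Genes were named by a rule fixed at the same time. It took the 10 largest rises and 10 largest falls per comparison among probe sets with 1 gene symbol, past the threshold and with no overlap between the arrays of the groups compared. It added up to 4 called members of each list with the largest changes, and 20 genes fixed by name. Of these 20, cyp1a and vegfaa lay below the filter on dim probe sets and were not tested, and hsp70l, hmox1a, gstp1, pdk2a and slc2a1a had no probe set matched to that gene alone. Another of them is not reported here. Symbols that are only clone or locus names were passed over.

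The fit was tested on simulated data with the real means of the 9301 probe sets and the spread that limma estimated for each. In these data 200 probe sets were changed in the 50 µg/L arrays. Over 10 simulated tables for the comparison of 50 µg/L with control, 18.4% of the probe sets changed by 1 on the log2 scale were called, 86.4% of those changed by 2, 98.8% of those changed by 3 and 99.6% of those changed by 4. Of the calls, 4.92% were false. The values were drawn from the normal distribution that limma assumes, with the same spread in every array. These rates therefore hold under the model and need not hold for the real arrays. A shift of -0.50 planted in the oxidative phosphorylation list was called by camera in 10 of 10 tables of 6112 genes for the same comparison, with 1 call among all other lists. The simulated values of each gene were drawn independently of other genes. In the real data the estimated correlation was 0.179 for oxidative phosphorylation and 0.433 for ribosomal proteins. The simulation therefore does not give the rate of false calls for lists of correlated genes.

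Alternatives covered the offset before log2, the filter, the scaling between arrays, the eBayes options, array weights, the replicate number as a block, the arrays in the fit, each array left out in turn, and the list tests. Alternatives on the export format, on 2 arrays left out together and on the background level were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.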

Results

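The series measured transcript levels in gastrula-stage zebrafish embryos exposed to pentachlorophenol, a chlorinated phenol used as a biocide and known as an uncoupler of oxidative phosphorylation. The groups were 20 µg/L, 50 µg/L and deionized water, with 3 arrays in each. Median signals lay between 97.9 and 151.9 per array, and those of the 50 µg/L arrays were the highest (151.9, 142.2 and 141.8). Control replicate 3 stood apart from the other arrays. Its median Spearman correlation with them was 0.847, and its tag control level of 113.8 was the highest. The next lowest correlation was that of 50 µg/L replicate 1 (0.878), against 0.906 to 0.922 for the rest. The first principal component held 39.5% of the variance and the second 20%.

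**Figure D1:**
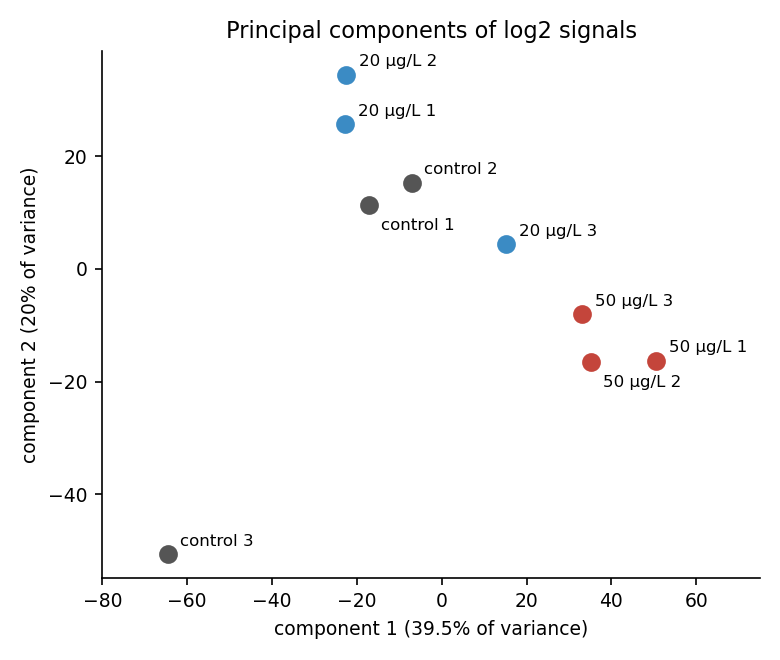
Each point is 1 of the 9 arrays on the first and second principal components (arbitrary units) of the log2 signals, coloured by group and labelled with its replicate number. The 50 µg/L arrays lie at 33.2 to 50.6 on component 1, control replicate 3 lies at -64.6, and 20 µg/L replicate 3 lies at 15.2, between the 50 µg/L arrays and the other 20 µg/L arrays.

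At 50 µg/L, genes of glycolysis and of the hypoxia response rose, gapdhs, egln3 and pfkfb3 among them. The glycolytic dehydrogenase gene gapdhs went from a signal of 127 in control embryos to 5393 ± 2051 (SD, n = 3), a log2 change of 5.39 (SE 0.83, limma adjusted p = 0.00844). The oxygen sensor prolyl hydroxylase gene egln3 rose by 5.23 (SE 0.81, adjusted p = 0.0084) and the collagen prolyl hydroxylase subunit gene p4ha1b by 3.86 (SE 0.51, adjusted p = 0.00754). The aldolase gene aldocb rose by 4.15 and the lactate dehydrogenase gene ldha by 3.98, with 2 of 3 control arrays under the tag control level, or 5.92-fold and 11.5-fold with dim values raised to it. A second probe set of aldocb was called too (adjusted p = 0.0282). The gene pfkfb3, which makes an activator of glycolysis, was under that level in all 3 control arrays and was at least 6.15-fold higher at 50 µg/L (adjusted p = 0.0246). Of 22 glycolysis and glucose uptake genes, 10 rose, 1 fell and 11 did not pass (14 rose and 1 fell adjusted over the list alone), with a list median of 1.14. Of 18 hypoxia response genes, 4 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.75, or 0.85 with dim values raised to the tag control level. The risers of that list were egln3, p4ha1b, pfkfb3 and igfbp1a, of which the last encodes a binding protein of insulin-like growth factors (log2 change 3.05, adjusted p = 0.049, second probe set 2.27 with adjusted p = 0.0821). The member of both lists that fell was pfkfb4b (-0.99, adjusted p = 0.0488), named after its values were seen. Among the 6 arrays deposited with 1 decimal the list medians were 1.15 and 1.02. Camera called both lists up (adjusted p = 5.07e-06 and 0.000797), and the calls were lost with an estimated correlation (adjusted p = 0.219 with an estimated correlation for glycolysis and adjusted p = 0.253 with an estimated correlation for hypoxia). The calls of gapdhs, egln3 and p4ha1b were lost without 50 µg/L replicate 1 (adjusted p = 0.0717, 0.0717 and 0.0648) and held without each other array. Those of ldha and aldocb were also lost without control replicate 1 or 50 µg/L replicate 2, that of aldocb without 50 µg/L replicate 3 and that of pfkfb3 without 50 µg/L replicate 2. The call of igfbp1a held in 2 of 9 such fits, without 20 µg/L replicate 3 or 50 µg/L replicate 3, and was lost without each control array, 20 µg/L replicates 1 and 2, and 50 µg/L replicates 1 and 2 (adjusted p up to 0.21). It was also lost in 7 of the 14 settings that leave out no single array (adjusted p up to 0.0742), among them the export format as a block (adjusted p = 0.0532).

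**Figure D2:**
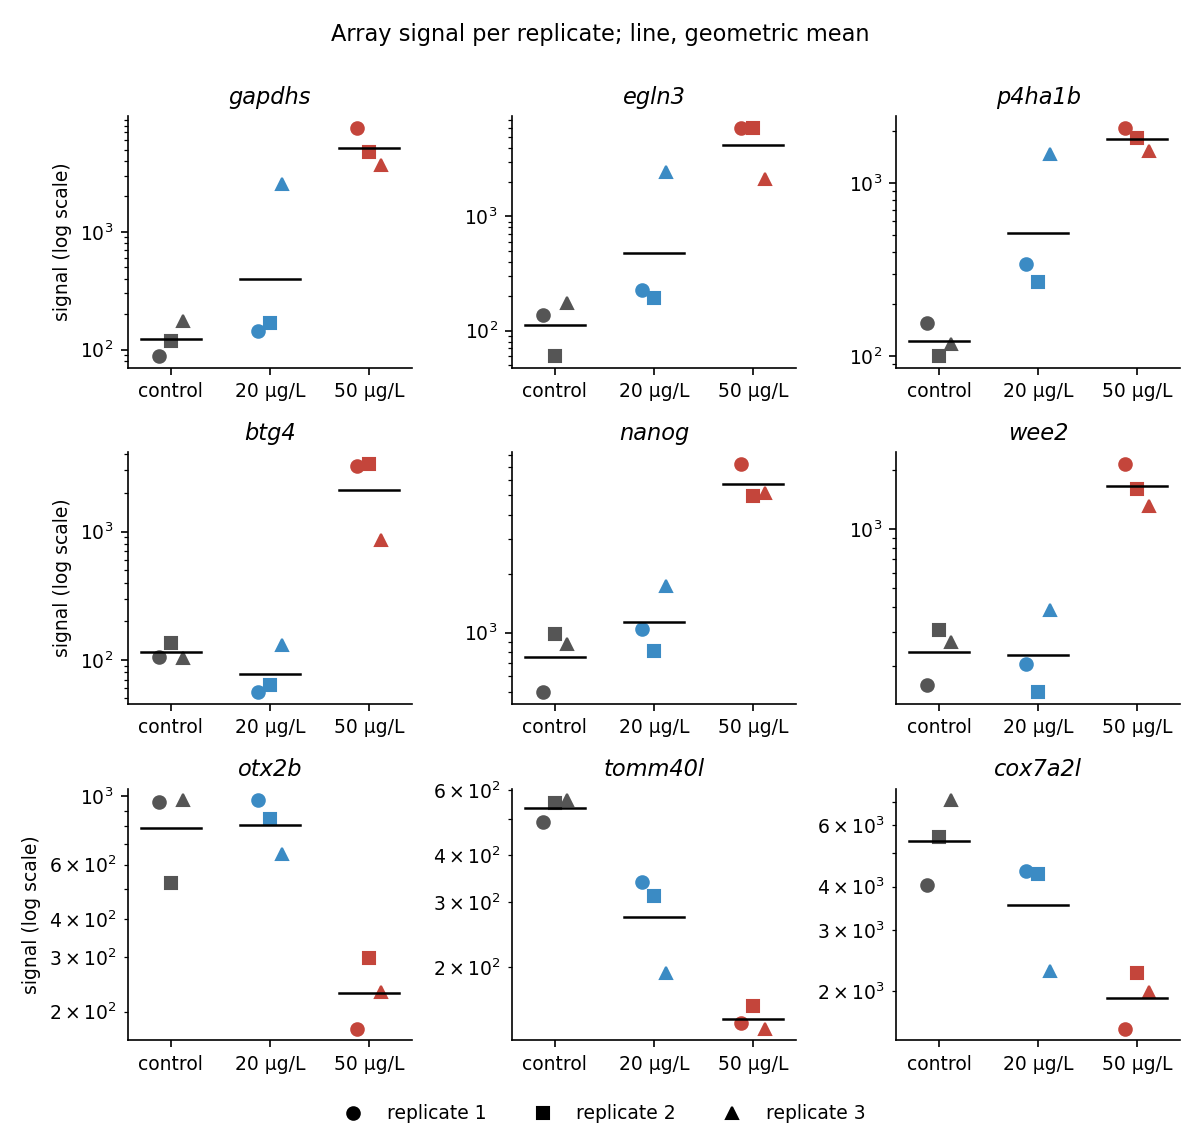
Array signal (log axis, arbitrary units) of 9 named genes in control, 20 µg/L and 50 µg/L embryos, with a symbol for each replicate and a line at the geometric mean. The 3 arrays at 50 µg/L lie apart from the 3 control arrays for each gene shown, which follows from the choice of genes called at 50 µg/L. The array of 20 µg/L replicate 3 is the highest 20 µg/L array for gapdhs, egln3 and p4ha1b.

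Transcripts that the oocyte supplies to the egg were higher at 50 µg/L. Of 32 germ cell and maternal oocyte genes, 9 rose, none fell and 23 did not pass (13 rose adjusted over the list alone), and the list median was 0.85. With 1 probe set standing for each gene, the largest rise of the list was in btg4, a factor in clearance of maternal mRNA, whose signal went from 115 to 2493 ± 1413 (SD, n = 3), a log2 change of 4.20 (SE 0.49, limma adjusted p = 0.00546). The claudin gene cldnd rose by 3.15 (adjusted p = 0.00546), the oocyte kinase gene wee2 by 2.80 (adjusted p = 0.00754) and the zinc finger gene cth1 by 2.77 (adjusted p = 0.0084). The 3 other probe sets of wee2 were called as well, with 3.40, 4.45 and 4.41. The pluripotency factor gene nanog, whose product acts in early zygotic transcription, rose by 2.92 (SE 0.34, adjusted p = 0.00546) and was the 1 called of 41 convergent extension and epiboly genes (1 rose adjusted over the list alone). Camera called the maternal list up (adjusted p = 2.24e-07, median 0.97 among the 6 arrays deposited with 1 decimal), and not with an estimated correlation (adjusted p = 0.189 with an estimated correlation). The calls of btg4, cldnd, wee2, cth1 and nanog were lost without 50 µg/L replicate 1 (adjusted p = 0.0566, 0.0566, 0.0648, 0.0717 and 0.0566) and held without each other array.

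Genes of the mitochondrial respiratory chain and ATP synthase fell at 50 µg/L. Of 81 oxidative phosphorylation genes, 16 fell, 1 rose and 64 did not pass (42 fell and 1 rose adjusted over the list alone), with a median log2 change of -0.64. The signal of cox7a2l fell from 5556 to 1935 ± 348 (SD, n = 3, log2 change -1.50, limma adjusted p = 0.0241), that of atp5mc1 from 7968 to 2889 (-1.40, adjusted p = 0.0245) and that of atp5md from 3280 to 1238 (-1.52, adjusted p = 0.0282). The member that rose, cox6b1, was under the tag control level in all 3 control arrays and was at least 3.21-fold higher (adjusted p = 0.0282). The pyruvate dehydrogenase subunit gene pdhb fell by 1.44 on the log2 scale and the succinate ligase gene sucla2 by 1.02 (adjusted p = 0.0488, second probe set -0.64 with adjusted p = 0.163). Those were the 2 of 29 pyruvate dehydrogenase and TCA cycle genes that passed, and the same 2 passed adjusted over the list alone. That list was not called, and its median (0.12) and mean (-0.03) differed in sign (camera adjusted p = 0.371). Of the 76 cytosolic ribosomal protein genes, 5 fell and none rose (40 fell and 1 rose adjusted over the list alone), with a median of -0.58. Examples were rps16 (-0.97), faua (-0.85), rpl35 (-0.84) and rpl27 (-0.81), with adjusted p = 0.0495, 0.0429, 0.0471 and 0.0463. Camera called oxidative phosphorylation (adjusted p = 5.21e-17) and ribosomal proteins (adjusted p = 1.71e-20) down, with medians of -0.61 and -0.45 among the 6 arrays deposited with 1 decimal, and neither with an estimated correlation (adjusted p = 0.189 with an estimated correlation and adjusted p = 0.241 with an estimated correlation). Each of these gene calls was lost without 50 µg/L replicate 1 (adjusted p up to 0.214). At least 1 was also lost without control replicate 1 or 3, without 20 µg/L replicate 1, 2 or 3, or without 50 µg/L replicate 2 or 3, and rps16 held in 1 of 9 such fits. Of the 14 settings that leave out no single array, rps16, rpl27 and sucla2 were lost in 7, faua in 6 and rpl35 in 5 (adjusted p up to 0.152), each of them without the filter and with the replicate number as a block. Among the 6 arrays deposited with 1 decimal these 5 genes had adjusted p = 0.11, 0.132, 0.0611, 0.119 and 0.106, and with the export format as a block sucla2 had adjusted p = 0.0516. The calls of atp5md (adjusted p = 0.0608 among the 6 arrays) and cox6b1 were lost in 2 such settings.

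**Figure D3:**
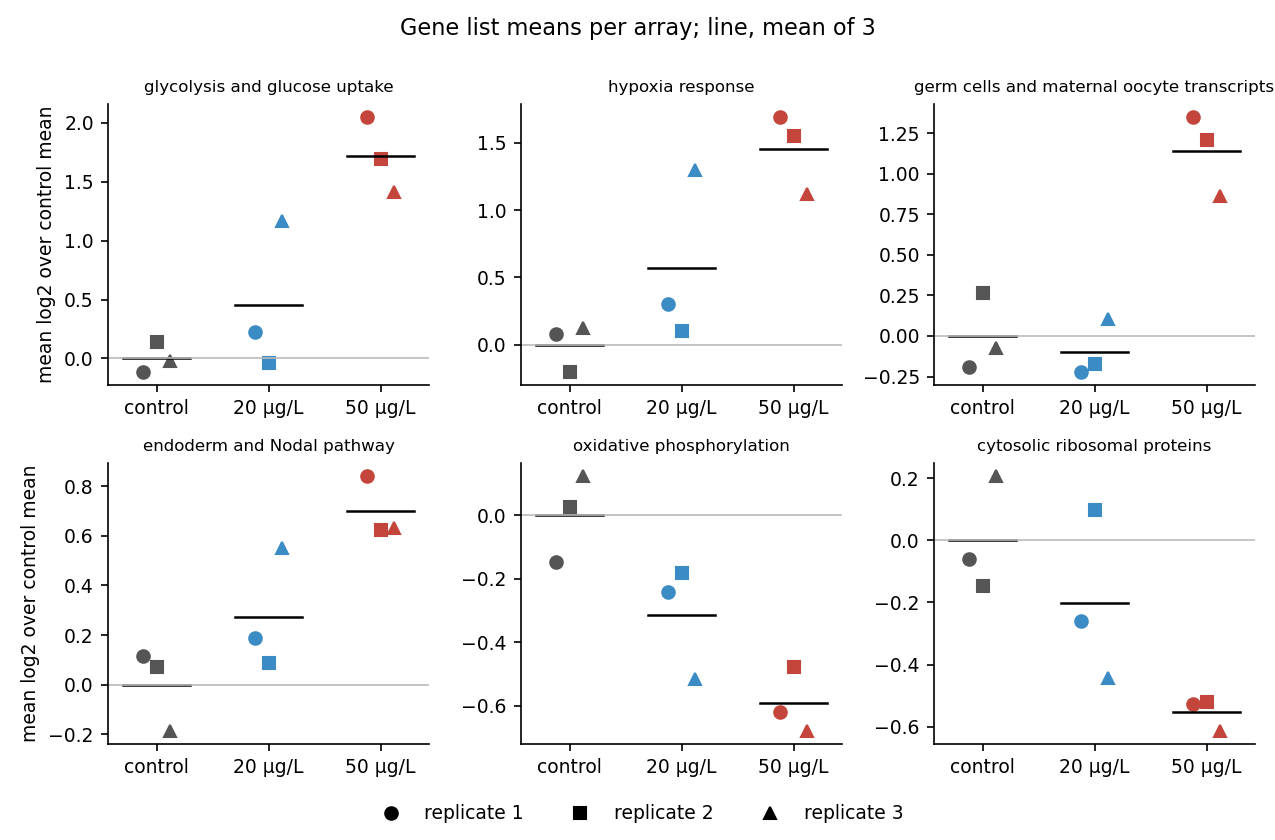
Mean log2 signal of the genes of 6 lists relative to the control mean (log2 units), per array, with a symbol for each replicate and a line at the mean of the 3 arrays of a group. For glycolysis, 20 µg/L replicate 3 lies at 1.17 while the other 20 µg/L arrays lie at 0.22 and -0.04, and for maternal transcripts it lies at 0.10.

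Genes of early germ layer patterning moved both ways at 50 µg/L. The homeobox genes otx2b and gbx1, which act in the anterior neural plate and hindbrain, fell by 1.77 and 1.62 on the log2 scale (limma adjusted p = 0.0156 and 0.00949). They were the 2 called of 34 neuroectoderm genes (3 fell adjusted over the list alone, median -0.27). Among 19 endoderm and Nodal pathway genes, mixl1 (2.63), cxcr4a (1.28) and gdf3 (1.21) rose and none fell (5 rose adjusted over the list alone, median 0.57, or 0.47 with dim values raised). Of 30 BMP pathway and ventral fate genes, the homeobox gene vent rose by 2.37 and the ligand gene bmp4 by 2.05 (adjusted p = 0.0271 and 0.0441), and 3 rose adjusted over the list alone. A second probe set of vent did not pass (1.79, adjusted p = 0.0756). The organizer gene gsc rose by 1.51 (adjusted p = 0.0424), as the 1 riser beside the fall of otx2b among 28 dorsal organizer and axial mesoderm genes, and hnf4a of the yolk syncytial layer list by 1.62 (second probe set 0.74, adjusted p = 0.372). The muscle actin gene actc1b fell by 1.63 on the log2 scale, with 2 of 3 exposed arrays under the tag control level and -1.22 with dim values raised to it (second probe set -1.42, adjusted p = 0.162), as the 1 called of 13 segmentation-stage genes. Of the genes fixed by name, tbxta (0.60), chrd (0.62), sox17 (0.15), bmp2b (-0.05), krt4 (-0.07) and myf5 (-0.40) did not pass, with adjusted p from 0.285 to 0.915. Camera called neuroectoderm down (adjusted p = 0.00611) and endoderm up (adjusted p = 0.00195), with medians of -0.21 and 0.39 among the 6 arrays deposited with 1 decimal, and neither with an estimated correlation (adjusted p = 0.253 with an estimated correlation and adjusted p = 0.241 with an estimated correlation). Neuroectoderm was not called with the lowest 60% of probe sets left out (adjusted p = 0.112). The gene calls were lost without 50 µg/L replicate 1 (adjusted p from 0.0717 to 0.191). Those other than mixl1 and gbx1 were also lost without at least 1 of control replicates 1, 2 and 3, 20 µg/L replicates 1 and 2 and 50 µg/L replicates 2 and 3. In settings that leave out no single array, bmp4 was lost in 7 of 14 (adjusted p = 0.0901 among the 6 arrays deposited with 1 decimal), gsc, cxcr4a and hnf4a in 4 of 14, actc1b in 3 of 13 and gdf3 in 1 of 14 (adjusted p up to 0.0901).

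Stress and cell cycle genes gave single calls at 50 µg/L. Of 37 endoplasmic reticulum stress and amino acid response genes, the phosphatase regulator gene ppp1r15a (log2 change 2.38) and the chaperone genes hsp90b1 (1.86) and hyou1 (1.38) rose, while the mitochondrial folate enzyme gene mthfd2 fell by 1.86 on the log2 scale (4 rose and 4 fell adjusted over the list alone). The main chaperone gene of that compartment, hspa5, had a log2 change of 1.24 and did not pass (limma adjusted p = 0.0546), while it passed with the export format as a block (adjusted p = 0.0473), among the 6 arrays deposited with 1 decimal (adjusted p = 0.0309) and without control replicate 2 (adjusted p = 0.0343). It passed as well with array weights (adjusted p = 0.00709), an offset of 32 (adjusted p = 0.0457) and dim values raised to the tag control level (adjusted p = 0.0414). Other probe sets of ppp1r15a had 3.16 (adjusted p = 0.0213), 2.68 (adjusted p = 0.0594) and 2.26 (adjusted p = 0.0572). Of 32 growth arrest and apoptosis genes, birc5b (2.28) and casp9 (1.72) rose, none fell and 30 did not pass (2 rose adjusted over the list alone). The ubiquitin ligase gene mdm2 had 1.08 and did not pass (adjusted p = 0.0763), while it passed with the replicate number as a block (adjusted p = 0.0467). Of 60 cell cycle and DNA replication genes, 5 rose, among them ccna1 (2.42), fbxo5 (1.13) and aurka (1.05), and the replication clamp gene pcna fell by 0.85 on the log2 scale (named after its values were seen, 8 rose and 1 fell adjusted over the list alone). The oocyte kinase gene wee2, a member of the maternal list too, was also among the 5. The glutathione synthesis gene gclc rose by 1.08 (adjusted p = 0.0487) as the 1 call of 30 oxidative stress genes (3 rose and 3 fell adjusted over the list alone). The chaperone genes dnaja2a and hspe1 fell by 1.28 and 0.96, the proteasome genes psma1 and psmb2 and the ubiquilin gene ubqln4 by 1.14, 1.09 and 1.09, and mycn and the nucleolar gene gnl3l by 1.14 and 1.05 on the log2 scale. Second probe sets of ubqln4 (-0.72, adjusted p = 0.274) and mycn (-0.65, adjusted p = 0.303) did not pass. The heat shock list (2 of 29 fell, 6 adjusted over the list alone, median -0.38), the proteasome list (3 of 52 fell, 7 fell and 1 rose adjusted over the list alone, median -0.39), ribosome biogenesis (2 of 50 fell, 2 adjusted over the list alone, median -0.14) and the pentose phosphate pathway (0 of 6 passed and 3 fell adjusted over the list alone, median -0.71) were called down by camera (adjusted p = 0.000236, 2.67e-06, 0.0294 and 0.00209). Among the 6 arrays deposited with 1 decimal their medians were -0.32, -0.51, -0.31 and -0.66. None of the 4 was called with an estimated correlation (adjusted p = 0.219, 0.189, 0.46 and 0.189, each with an estimated correlation), and ribosome biogenesis was not called under quantile normalization, nor without control replicate 1, control replicate 2 or 50 µg/L replicate 1 (adjusted p = 0.319, 0.2, 0.191 and 0.0624). Its call was also lost with the lowest 60% of probe sets left out (adjusted p = 0.0907) and with the mean of all probe sets of a gene (adjusted p = 0.118). The hexokinase gene hk1 (-0.39, adjusted p = 0.346) and the uncoupling protein gene ucp2 (-0.72, adjusted p = 0.094) did not pass, and ucp2 did with array weights (-0.61, adjusted p = 0.0423). Without 50 µg/L replicate 1 none of these gene calls held (adjusted p from 0.0648 to 0.191 for those other than pcna). Those other than casp9, ccna1, mthfd2 and wee2 were also lost without at least 1 of control replicates 1, 2 and 3, 20 µg/L replicates 1 and 2 and 50 µg/L replicates 2 and 3. Of the 14 settings that leave out no single array, gclc and psma1 were lost in 7, ubqln4 in 6, hsp90b1 in 5, aurka and psmb2 in 4, hyou1, mycn and gnl3l in 3, and fbxo5 and hspe1 in 2 (adjusted p up to 0.142). Among the 6 arrays deposited with 1 decimal psma1, ubqln4, hsp90b1, psmb2, mycn, gnl3l and fbxo5 did not pass (adjusted p from 0.0504 to 0.142), and with the export format as a block gclc did not (adjusted p = 0.0516).

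Outside these lists, the cyclin gene ccnp (log2 change 4.54, or 13.9-fold with dim values raised to the tag control level), the syntaxin gene stx11a (4.37, or 7.29-fold so raised, second probe set 2.70, both called) and the importin gene kpna7 (3.65, or 6.18-fold so raised) rose at 50 µg/L. Of the control arrays, 1 of 3 was under that level for ccnp and 2 of 3 for stx11a and kpna7. Genes that fell were the urea transporter gene slc14a2, which was under the tag control level in all 3 exposed arrays and at least 3.38-fold lower (limma adjusted p = 0.00964), and the mitochondrial import gene tomm40l (-1.88, limma adjusted p = 0.0084). The genes sap30bp (-1.55) and rbbp4 (-1.54), whose product binds histones, fell too, as did the chemokine gene ccl19a.1, under that level in the 3 exposed arrays and at least 2.02-fold lower. These calls were lost without 50 µg/L replicate 1 (adjusted p from 0.0648 to 0.178), and those of ccnp, kpna7, sap30bp, rbbp4 and ccl19a.1 also without at least 1 of control replicates 1, 2 and 3, 20 µg/L replicates 1 and 2 and 50 µg/L replicates 2 and 3. In settings that leave out no single array, sap30bp was lost in 2 of 14 and ccl19a.1 in 6 of 13 (adjusted p = 0.111 among the 6 arrays deposited with 1 decimal). The call of ccl19a.1 was among those lost with dim values raised to the tag control level, so its 2.02-fold bound is not that of a called change. In all, 417 of 9301 probe sets changed at 50 µg/L, 321 up and 96 down, 394 of them by at least 2-fold. At an unadjusted p under 0.05 the count was 2281. All 417 had no overlap between the 3 exposed and the 3 control arrays, as had 28.2% of the probe sets tested, where chance gives 10%. The direction of the calls depended on the scaling between arrays. With each array centred on its median, 156 probe sets rose and 160 fell, and with quantile normalization 204 rose and 120 fell. The median log2 change of all probe sets was 0.10 as deposited, -0.15 with median centring and -0.04 with quantile normalization. The limma count was 0 without 50 µg/L replicate 1 (1486 at an unadjusted p under 0.05), 81 without replicate 2 and 160 without replicate 3 of that group, 168 without control replicate 1, 721 without control replicate 2, 207 without 20 µg/L replicate 1 and 200 without 20 µg/L replicate 2. With the export format as a block it was 458, and among the 6 arrays deposited with 1 decimal it was 452. Camera called the 11 lists with the block too, and among those 6 arrays the 11 and the enveloping layer (down, adjusted p = 0.0227).

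**Figure D4:**
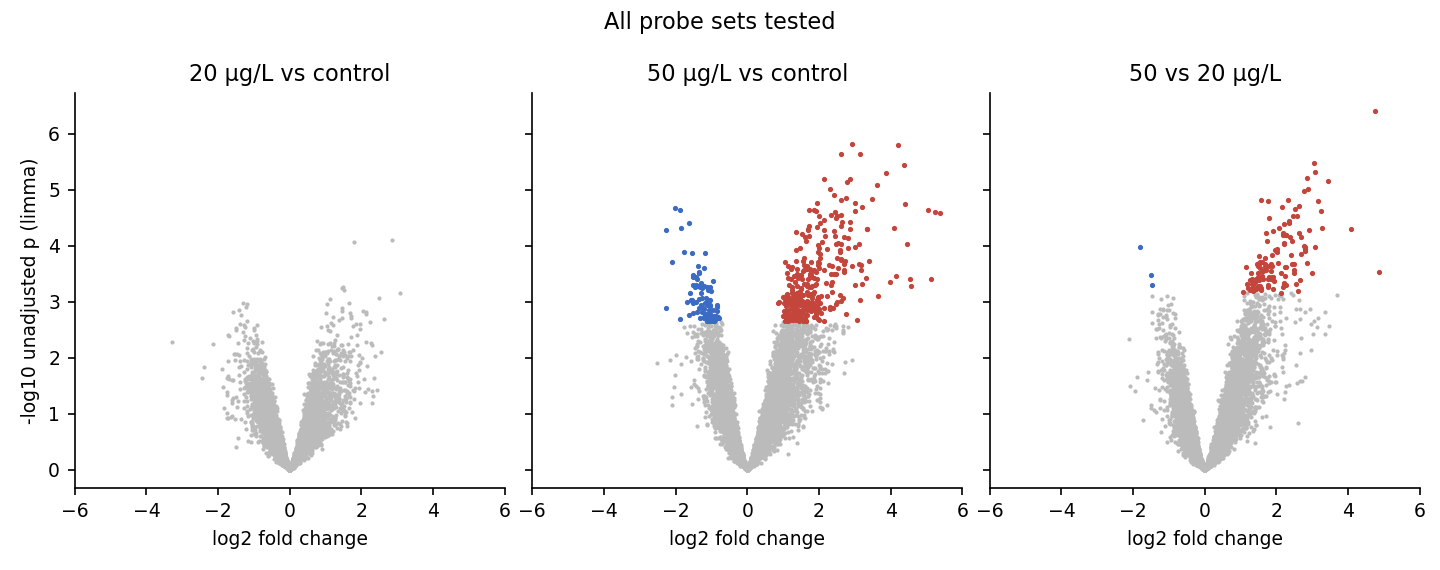
Log2 fold change against -log10 of the unadjusted limma p for the 9301 probe sets tested in each comparison. Red and blue points are those past the adjusted threshold of 0.05, higher and lower, and grey points are the rest, with 0 calls at 20 µg/L, 417 at 50 µg/L and 129 between the doses.

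At 20 µg/L no single gene passed the test against control. Limma called 0 of 9301 probe sets, with 731 at an unadjusted p under 0.05, and 12.7% had no overlap between the groups where chance gives 10%. The signal of ldha was 143 ± 159 (SD, n = 3) against 62.9 in control (log2 change 0.86, adjusted p = 0.802), and the change was -0.04 without 20 µg/L replicate 3. In that array gapdhs read 2575 and egln3 2449, against 143 and 168 for gapdhs and 228 and 193 for egln3 in replicates 1 and 2. The organizer gene chrd had a log2 change of 1.18 (SE 0.42, adjusted p = 0.61), and hk1 (0.14), mdm2 (0.45), ucp2 (-0.49), hspa5 (0.08), gsc (0.13), tbxta (0.13), sox17 (0.21), bmp2b (-0.10), krt4 (-0.04) and myf5 (-0.29) did not pass either (adjusted p from 0.638 to 0.96). Camera called 8 lists. None was called with an estimated correlation (adjusted p = 0.513 to 0.648 with an estimated correlation) or by fry (adjusted p = 0.431 to 0.495). Glycolysis (median 0.30, adjusted p = 0.0133), hypoxia (0.20, adjusted p = 0.00551), ribosome biogenesis (0.16, adjusted p = 0.00855), BMP pathway (0.19, adjusted p = 0.0178) and endoderm (0.22, adjusted p = 0.0294) were up. Oxidative phosphorylation (-0.33, adjusted p = 2.9e-07), ribosomal proteins (-0.22, adjusted p = 0.000198) and oxidative stress (-0.22, adjusted p = 0.037) were down. Of the 8 lists, 1, ribosome biogenesis, was called without 20 µg/L replicate 3, 4 without control replicate 2 and 3 without control replicate 3. Without control replicate 1 glycolysis (adjusted p = 0.0664) and endoderm (adjusted p = 0.0569) were lost, and without 20 µg/L replicate 2 ribosome biogenesis was lost (adjusted p = 0.0898). With the export format as a block 8 lists and 0 probe sets were called (804 at an unadjusted p under 0.05), and among the 6 arrays deposited with 1 decimal none of the 8 was called and 1 other was, the enveloping layer (down, adjusted p = 0.00551). There the medians were 0.04 for glycolysis and -0.13 for oxidative phosphorylation. Those of ribosomal proteins (0.02) and endoderm (-0.01) had the opposite sign. Convergent extension was not called (adjusted p = 0.0707) but was up without control replicate 1, 20 µg/L replicate 1 or 20 µg/L replicate 2 (adjusted p = 0.0154, 0.0278 and 0.0141), with no filter (adjusted p = 0.0202) and with dim values raised to the tag control level (adjusted p = 0.0474). Ventrolateral mesoderm (adjusted p = 0.0707) was up without 20 µg/L replicate 2 (adjusted p = 0.017) and with dim values so raised (adjusted p = 0.0474). Dorsal organizer genes (adjusted p = 0.182) were up without 20 µg/L replicate 2 (adjusted p = 0.0464). Cell cycle genes (adjusted p = 0.115) were up with no filter (adjusted p = 0.0349) and with the mean of all probe sets of a gene (adjusted p = 0.0171). The enveloping layer list (adjusted p = 0.148) was down without control replicate 3 (adjusted p = 0.0181). The count of probe sets was 1 without control replicate 2 and 1 without 20 µg/L replicate 3, and 22 among the 6 arrays deposited with 1 decimal.

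Between the doses, maternal oocyte transcripts were higher at 50 µg/L, with 8 of 32 genes called. At 50 against 20 µg/L, btg4 was higher by 4.76 on the log2 scale (SE 0.49, limma adjusted p = 0.00374), with 2493 against 82.7. The autophagy gene map1lc3c (3.16), cldnd (3.04), ccna1 (2.89), wee2 (2.85, with 3 other probe sets not called, adjusted p from 0.0803 to 0.141), sinup (2.91), gtf3ab (2.80), ppp1r3c2b (2.80) and pias4b (3.08, or 2.71 with dim values raised to the tag control level) were higher too. Of the 20 µg/L arrays, 2 of 3 were under that level for btg4, pias4b and slbp2. Also higher were the oocyte histone mRNA binding gene slbp2 (3.00, or 2.23 with dim values raised to the tag control level), nanog (2.33), mixl1 (2.27), birc5b (2.26), the lactate transporter gene slc16a3b (2.25), hyou1 (1.61), casp9 (1.30) and gins2 (1.25). The genes that were lower were otx2b (-1.81), the mitochondrial import gene tomm40 (-1.51) and hnrnpua (-1.47). A probe set of aldocb with 2 of 3 arrays at 20 µg/L under the tag control level was called (adjusted p = 0.0355), while the brighter one that stood for that gene was not (3.03, adjusted p = 0.1). Of the maternal oocyte genes, 8 were higher and none lower (16 higher adjusted over the list alone, median 0.995), and of the 22 glycolysis genes 1 was higher (11 higher and 1 lower adjusted over the list alone, median 0.98). Camera called both up (adjusted p = 1.74e-09 and 0.000241) and 8 lists down. None of the 10 was called with an estimated correlation (adjusted p = 0.226 to 0.309 with an estimated correlation). The lists that were down were ribosomal proteins (median -0.36, adjusted p = 8.1e-14), oxidative phosphorylation (-0.38, adjusted p = 1.19e-08) and ribosome biogenesis (-0.36, adjusted p = 4.38e-07), followed by heat shock (-0.39, adjusted p = 5.33e-06), proteasome (-0.38, adjusted p = 1.27e-05), neuroectoderm (-0.17, adjusted p = 0.0079), the pentose phosphate pathway (-0.48, adjusted p = 0.0151) and segmentation-stage genes (-0.20, adjusted p = 0.0472). Neuroectoderm was lost among the 6 arrays deposited with 1 decimal (adjusted p = 0.236), with the lowest 60% of probe sets left out (adjusted p = 0.12), without control replicate 3 and 20 µg/L replicate 3 together (adjusted p = 0.0888) and without 20 µg/L replicate 3 alone (adjusted p = 0.0535). The pentose phosphate pathway was lost under quantile normalization (adjusted p = 0.0642). Segmentation-stage genes were lost with the export format as a block (adjusted p = 0.0541), with the replicate number as a block (adjusted p = 0.0568) and among the 6 arrays (adjusted p = 0.309). That call was also lost without control replicate 3, 20 µg/L replicate 3 or 50 µg/L replicate 3 (adjusted p = 0.055, 0.147 and 0.128) and in 7 other settings of the fit or its values (adjusted p up to 0.405). The hypoxia list was not called (median 0.52, adjusted p = 0.0728). It was called up among the 6 arrays deposited with 1 decimal (adjusted p = 0.00223), without 20 µg/L replicate 3 (adjusted p = 0.00791) or 50 µg/L replicate 3 (adjusted p = 0.0428), and without control replicate 3 and 20 µg/L replicate 3 together (adjusted p = 0.00741). Median centring (adjusted p = 0.0145), array weights (adjusted p = 0.03) and dim values raised to the tag control level (adjusted p = 0.0393) gave that call too. Endoderm was up under quantile normalization (adjusted p = 0.0259) and with the lowest 60% left out (adjusted p = 0.0167). Ventrolateral mesoderm was down without 20 µg/L replicate 2 (adjusted p = 0.0243). The TCA cycle list was down among the 6 arrays (adjusted p = 0.049). Fry called 3 of the 10, glycolysis, the pentose phosphate pathway and maternal transcripts (adjusted p = 0.0395, 0.0395 and 0.00762). It called 3 others up, endoplasmic reticulum stress, growth arrest and apoptosis, and cell cycle (adjusted p = 0.0198, 0.0107 and 0.0187). In all, 129 probe sets differed, 126 higher and 3 lower, with 1717 at an unadjusted p under 0.05. With median centring 20 were higher and 3 lower, and with quantile normalization 49 and 4. The export format as a block gave 158 probe sets and 9 lists, and the 6 arrays deposited with 1 decimal gave 1171 probe sets and 10 lists, 8 of them called in all arrays too. Among those 6 arrays the median was 1.03 for maternal and 1.23 for glycolysis genes. The count was 1 without 20 µg/L replicate 1, 1 without 20 µg/L replicate 2, 1 without 50 µg/L replicate 1 and 2 without 50 µg/L replicate 2, while it was 449 without 20 µg/L replicate 3 and 329 without control replicate 3. The call of btg4 held in 9 of 9 of these fits, and each other gene call named here was lost in at least 3 of them. The arrays left out in those fits were 20 µg/L replicates 1, 2 and 3, 50 µg/L replicates 1, 2 and 3 and control replicate 1. In settings that leave out no single array, casp9, gins2 and slc16a3b were lost in 4 of 14, birc5b and tomm40 in 3 of 14, slbp2 in 3 of 13, hyou1, hnrnpua and ppp1r3c2b in 2 of 14, and gtf3ab, mixl1, otx2b and sinup in 1 of 14 (adjusted p up to 0.114). The changes of ldha (3.12, adjusted p = 0.0884) and gsc (1.38, adjusted p = 0.0879) did not pass, while both passed without control replicate 3 (adjusted p = 0.0478 and 0.0428) or 20 µg/L replicate 3 (adjusted p = 0.0205 and 0.0344), and gsc without 50 µg/L replicate 3 (adjusted p = 0.0495). Both also passed with array weights (adjusted p = 0.00232 and 0.00243), without control replicate 3 and 20 µg/L replicate 3 together (adjusted p = 0.00468 and 0.00875), with only the groups compared (adjusted p = 0.0446 and 0.0451) and among the 6 arrays (adjusted p = 0.000499 and 0.00132). With dim values raised ldha passed (adjusted p = 0.0323). The gene hspa5 (1.16, adjusted p = 0.106) passed with array weights (adjusted p = 0.00652), without that pair of arrays (adjusted p = 0.0233) and among the 6 arrays (adjusted p = 0.00776).

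Across probe sets, which are not independent replicates, the log2 changes of both doses had a Pearson correlation of 0.538 and a Spearman correlation of 0.498. Over all probe sets 66.9% had the same sign at both doses, while unchanged groups simulated against the same control arrays gave 63.4% on average (34.8% to 87.9% in 95% of 100 simulations). Both comparisons used the same control arrays, and unchanged groups simulated against them gave a mean correlation of 0.379 (95% of 100 simulations from -0.428 to 0.922). The covariance was 0.2 against a simulated 0.0704 (-0.0486 to 0.301), a difference of 0.13. Each of these observed values lay inside the range of the unchanged groups. Part or all of the excess may come from the shared controls, which were too few to split. The F test over both doses called 164 probe sets, with 1995 at an unadjusted p under 0.05. With the export format as a block it called 189, and among the 6 arrays deposited with 1 decimal 820. The limma F count was 0 without 50 µg/L replicate 1 (1137 at an unadjusted p under 0.05) and 0 without 50 µg/L replicate 2 (1537 at an unadjusted p under 0.05), 100 without 50 µg/L replicate 3, 76 without 20 µg/L replicate 1, 84 without 20 µg/L replicate 2, 427 without 20 µg/L replicate 3, 359 without control replicate 2 and 323 without control replicate 3.

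The remaining lists were not called by camera at 50 µg/L. Mitochondrial uncoupling and biogenesis had a median log2 change of -0.20 (adjusted p = 0.322), aryl hydrocarbon receptor and xenobiotic metabolism 0.24 (adjusted p = 0.585), thyroid and steroid hormone signalling 0.10 (adjusted p = 0.818) and lipid and cholesterol metabolism 0.17 (adjusted p = 0.819). Oxidative stress and glutathione had 0.05 (adjusted p = 0.707), the endoplasmic reticulum stress list 0.04 (adjusted p = 0.933), growth arrest and apoptosis 0.26 (adjusted p = 0.371) and cell cycle and DNA replication 0.14 (adjusted p = 0.324). Dorsal organizer and axial mesoderm had 0.21 (adjusted p = 0.92), BMP pathway and ventral fate 0.17 (adjusted p = 0.707), ventrolateral and paraxial mesoderm 0.01 (adjusted p = 0.822) and convergent extension and epiboly 0.28 (adjusted p = 0.371). Segmentation-stage genes had -0.25 (adjusted p = 0.0842), enveloping layer and epidermal keratins -0.07 (adjusted p = 0.0669), and the yolk syncytial layer -0.03 (adjusted p = 0.585). The enveloping layer list was called down without control replicate 3 (adjusted p = 0.00516) and without 50 µg/L replicate 1 or 2 (adjusted p = 0.0438 and 0.0328). It was also called without control replicate 3 and 20 µg/L replicate 3 together (adjusted p = 0.00695), with array weights (adjusted p = 0.00651), median centring (adjusted p = 0.0234), the mean of all probe sets of a gene (adjusted p = 0.0429) and no filter (adjusted p = 0.0481). Segmentation-stage genes were called down without control replicate 2 (adjusted p = 0.0457) and with no filter (adjusted p = 0.0377). Fry called 11 lists, 9 of them called by camera. It did not call ribosome biogenesis (adjusted p = 0.394) or neuroectoderm (adjusted p = 0.0594). The other lists it called were growth arrest and apoptosis (adjusted p = 0.0122) and cell cycle (adjusted p = 0.00688), both up. Quantile normalization also gave a camera call of cell cycle genes, upward (adjusted p = 0.0116). For oxidative stress, endoplasmic reticulum stress, thyroid and steroid signalling and ventrolateral mesoderm the camera direction was down while the median and mean were above 0. For the yolk syncytial layer the mean was 0.06, while the median and the camera direction were down. With dim values raised to the tag control level the medians were -0.04 for mitochondrial uncoupling, 0.12 for xenobiotic metabolism, and 0.01 for thyroid and steroid signalling. They were 0.19 for convergent extension, 0.20 for growth arrest and apoptosis and -0.10 for the yolk syncytial layer.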

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

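The tests of the maternal transcripts and of 20 µg/L replicate 3 were chosen after the results were seen, and those of bright probe sets and of other splits of the arrays before.

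The change against control differed between the doses for 129 probe sets, by the direct test of 50 against 20 µg/L. The manufacturer's GAPDH control probe sets, which no comparison used, were higher at 50 µg/L than in control embryos, by 5.67 for the 3' set, 4.63 for the middle set and 5.51 for the 5' set on the log2 scale. They are taken to read the transcript of gapdhs, so they repeat that result on the same arrays and are not a separate finding. The 3' set read 7791, 4225 and 4278 in the 50 µg/L arrays, 147, 93.5 and 2549 in the 20 µg/L arrays, and 180, 95.7 and 59.5 in control.

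Maternal oocyte transcripts were higher at 50 µg/L, with a list median of 0.85. Scaling between arrays is argued against as the whole cause, since under quantile normalization the median was 0.64 and 8 of the 9 called genes were still called. Embryos at an earlier stage at 50 µg/L may account for it. The segmentation-stage genes had a median of -0.25 there with a fry adjusted p of 0.162, which leaves that open. Of the 42 genes of that list on the array, 13 were past the filter on dim probe sets. The list could therefore show little of a difference in stage. A direct effect of pentachlorophenol on transcript clearance stays open too and was not tested, and the labels say that embryos were picked by stage.

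Glycolysis and hypoxia genes were higher in 20 µg/L replicate 3 than in the other 20 µg/L arrays. It also lay near the 50 µg/L arrays in the mean of the oxidative phosphorylation list (-0.52, against -0.68 to -0.48 at 50 µg/L and -0.24 and -0.18 in the other 20 µg/L arrays), the ribosomal proteins (-0.445, against -0.61 to -0.52, and -0.26 and 0.10) and the pentose phosphate pathway (-0.445, against -0.69 to -0.59, and -0.10 and -0.10), as RNA from a 50 µg/L sample would give. In other lists it lay the other way, above the 50 µg/L arrays and the other 20 µg/L arrays. The heat shock mean was 0.24 in it, against -0.49 to -0.14 at 50 µg/L and -0.17 and -0.12 in the other 20 µg/L arrays. Neuroectoderm (0.02, against -0.455 to -0.19, and -0.13 and -0.225) and segmentation-stage genes (0.10, against -0.625 to -0.22, and -0.09 and -0.13) went likewise. RNA from a 50 µg/L sample would bring all transcripts alike. The 13 called glycolysis and hypoxia genes reached a median of 44.6% of the 50 µg/L signal in that array (24.3% to 77.3%). The 9 called maternal genes reached 9.85% (-15% to 15.1%, two-sided permutation p = 0.00201). The permutation took the genes of 1 array as independent, so its p measures no spread between samples. These shares are not those of an even mixture, but they come from 1 array. Some of the lists above go with such RNA and others do not. A mixture or a wrong label is therefore not settled. Over the same genes 20 µg/L replicate 3 exceeded its group by 2.47 (SE 0.29 over genes), control replicate 3 by 0.22 (SE 0.18) and 50 µg/L replicate 3 by -1.10 (SE 0.19). A like rise was thus not seen in the other arrays with number 3. Each of these values rests on 1 array, the SEs measure no spread between arrays, and the genes were already high at 50 µg/L. Handling shared by the arrays with number 3 is therefore not settled either. A response of that sample alone to 20 µg/L is a hypothesis that stays open and was not tested.

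Oxidative phosphorylation and ribosomal protein genes were lower at 50 µg/L, and both lists are bright. Random lists of other genes matched on mean signal to the oxidative phosphorylation list had a median of -0.0639 (95% of 10000 lists from -0.21 to 0.10), against -0.64 for the list itself. Lists matched to the ribosomal proteins had -0.25 (-0.32 to -0.18) against -0.58. Other genes as bright thus fell less than either list, which argues against brightness as the whole cause. Part of the fall of the ribosomal proteins was shared by other bright genes. The ranges came from genes drawn 1 by 1 and ignore the correlation within the lists (estimated at 0.179 and 0.433). They are therefore too narrow to say how far the difference lies beyond chance. An effect of the uncoupler, which was not tested, and a difference in stage stay open.

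Each comparison of 3 with 3 arrays has 10 splits, too few for a share under 0.05. At 50 µg/L the real split gave 417 probe sets (1 of 10 splits as large, highest other 1) and 11 lists (1 of 10, highest other 8). Between the doses it gave 129 probe sets (1 of 10, highest other 0) and 10 lists (3 of 10, highest other 11). At 20 µg/L it gave 0 probe sets (10 of 10, highest other 0) and 8 lists (2 of 10, highest other 8). For the F test, 2 of 100 drawn splits of 280 gave at least the real 164 probe sets, the real one included, a share under 0.05. Such counts were thus rare among the splits drawn. The real split did not give the highest count, so the test does not single out the 3 groups as labelled. The highest other split gave 211, and the 3 other splits with the most calls (211, 130 and 124) kept the 50 µg/L arrays together and mixed the 20 µg/L and control arrays, so the structure the F test finds is mainly that of the 50 µg/L arrays.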

How the results depend on the processing

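The export format as a block, the 6 arrays deposited with 1 decimal, leaving out control 3 and 20 µg/L replicate 3 together, and low values raised to the tag control level were chosen after seeing the data, and the others before. Of 77 called results for named genes, 0 reversed and 37 stayed past the threshold in every setting other than leaving out an array, while 15 of 34 uncalled results changed sign and 6 gained a call in some setting. The cause of the differences given here was not tested, except that fewer arrays enter a fit that leaves some out and fewer or more probe sets enter one with another filter. Signal over background limits dim probe sets.

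Leaving out each array in turn, probe sets called ranged from 0 to 1 at 20 µg/L, 0 to 721 at 50 µg/L, 1 to 449 between the doses and 0 to 427 for the F test, and lists from 1 to 10, 10 to 12 and 9 to 11. A group left with 2 arrays shared its spread with the others. The correlation of the fold changes (0.538) ranged from 0.512 to 0.6 over a filter, an offset and quantile normalization.

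At 20 µg/L (0 probe sets by limma, 731 at an unadjusted p under 0.05), 4 were called without control 3 and 20 µg/L replicate 3, and 22 in the 6 arrays. At 50 µg/L (417), array weights gave 1724, no filter 277, and only the 2 groups compared 196. Between the doses (129), array weights gave 1934, median centring 23, the pair left out 1217, the tag control level 279, no filter 79, an offset of 32 195, only the 2 groups compared 393, the 6 arrays 1171, and quantile normalization 53. For the F test (164), array weights gave 2128, median centring 92, the pair left out 984, the tag control level 317, an offset of 32 258, and the 6 arrays 820. Of the 417 probe sets, 251 were shared with median centring, 264 with quantile normalization and 289 with the 6 arrays.

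The replicate numbers showed no clear pairing of the arrays. Of 9 same-numbered pairs, 1 had a rounded correlation over 0.1, and 4 of 9 arrays correlated best with their own number. The same-numbered pairs of 50 µg/L and control arrays had 0.1, 0.23 and 0.1, and the other same-numbered pairs had -0.16 to 0.095. These values do not settle whether the numbers mark pairs. With the replicate block 240 probe sets were called at 50 µg/L, 54 between the doses, 74 by the F test and 0 at 20 µg/L, and mdm2 at 50 µg/L passed (adjusted p = 0.0467).

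Of 8 lists at 20 µg/L, 5 were also called with the lowest 60% left out, 4 under quantile normalization, and 0 with an estimated correlation, by fry, with array weights, with the pair left out or in the 6 arrays. Each of the last 3 settings called 1 other list, that of the enveloping layer (adjusted p = 0.00216, 0.0121 and 0.00551). An estimated correlation left 0 of 11 at 50 µg/L and 0 of 10 between the doses, where fry called 6 lists, 3 of the 10 and 3 others. The ribosomal proteins at 20 µg/L turned upward with the pair left out (camera adjusted p = 0.305) and in the 6 arrays (0.354), against 0.000198 downward.

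For single genes, the sign changes were all of uncalled log2 changes. With the pair left out, at 20 µg/L gsc had -0.40, hspa5 -0.28, sox17 -0.25 and tbxta -0.12, at 50 µg/L sox17 had -0.17 and between the doses myf5 had 0.099 and sox17 0.0845. In the 6 arrays, at 20 µg/L gsc had -0.40, hspa5 -0.28, sox17 -0.25 and tbxta -0.12, at 50 µg/L chrd had -0.0666 and sox17 -0.0657 and between the doses bmp2b had -0.0516, myf5 0.31 and sox17 0.19. With median centring, at 20 µg/L bmp2b had 0.018 and krt4 0.0771, at 50 µg/L sox17 had -0.11 and between the doses bmp2b had -0.32. Under quantile normalization, at 20 µg/L krt4 had 0.0694, at 50 µg/L bmp2b had 0.0326, krt4 0.30 and sox17 -0.064 and between the doses krt4 had 0.23. With array weights, at 20 µg/L gsc had -0.0876 and hspa5 -0.014, at 50 µg/L chrd had -0.16 and between the doses krt4 had 0.0219, myf5 0.015 and sox17 0.13. Leaving out 1 array, the changes at 20 µg/L ranged for bmp2b from -0.22 to 0.0265, gsc from -0.16 to 0.36, hspa5 from -0.14 to 0.31, krt4 from -0.14 to 0.0318, ldha from -0.037 to 1.5, sox17 from -0.10 to 0.46 and tbxta from -0.13 to 0.45. At 50 µg/L the ranges were bmp2b from -0.20 to 0.0805 and sox17 from -0.17 to 0.39. Between the doses the ranges were bmp2b from -0.0998 to 0.16, krt4 from -0.10 to 0.0674, myf5 from -0.29 to 0.10 and sox17 from -0.36 to 0.14.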

Other observations

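Poly-A spike-in transcripts, added in the laboratory, differed between arrays. The signal of the dap spike-in was 16510 in control replicate 3 and 10910 in 20 µg/L replicate 1, against 2424 to 7357 in the other arrays. No explanation was tested.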
